A study of Epinephelus coioides with 9 samples.

How the data were processed

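RNA was measured in skin of the orange-spotted grouper *Epinephelus coioides*, a marine fish, after local infection with *Cryptocaryon irritans*, a ciliate that lives on the skin and gills of marine fish. Per the labels, 3 groups of 3 biological replicates were sequenced: skin of control fish, non-infected skin of infected fish and infected skin of infected fish. Libraries were made from polyadenylated RNA with an Illumina TruSeq kit, per the labels' protocols. Bowtie2 is named in the submitters' processing notes, with no version. Its role, the counting program and the sequences that reads were aligned to are not given in the sources used here. The labels do not say whether the non-infected and infected samples came from the same fish, nor whether a sample is 1 fish or a pool.

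The authors deposited 1 table of 91082 unigenes, which are assembled transcript sequences, with a length in bases, a count and an RPKM value per library. The deposited counts are whole numbers and were not normalised. Whether reads or fragments were counted is not stated in the file header. The deposited RPKM values equal the count scaled by unigene length and 1 library total, with a largest relative deviation of 2.58e-07 over all unigenes. That library total is larger than the sum of the deposited counts, which made up 90.1% of it in control libraries and 93.5% in the other 6. Unigene lengths ran from 201 to 22587 bases with a median of 800. The lowest count of a unigene summed over the 9 libraries was 11, so rarer sequences are not analysed here. The table pairs no unigene with a gene name or species. A reference table of 28384 genes of the same species, assembly ASM5131402v1, was searched for the unigene identifiers and 0 matched. Several unigenes can come from 1 gene, and reads shared between similar unigenes may be split in ways the table does not show, so counts of unigenes are not counts of genes.

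Count totals ranged from 36808364 to 57525765 per library. At those totals a count of 0 allows up to 3 counts, which is 0.0522 to 0.0815 CPM (counts scaled to a common library total); such limits cover counting error only. Replicates of a group were compared by a chi-square of their counts, and no pair agreed within sampling noise (chi-square per degree of freedom from 65.3 to 157), so all 9 libraries were kept as separate samples.

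Counts were tested with edgeR 4.0.16 in R 4.3.3. Unigenes with low counts were left out with the filterByExpr rule, libraries were scaled by TMM factors, and a quasi-likelihood model with group means was fitted to all 9 libraries. Each of the 3 comparisons was a contrast of that fit, with an F-test and Benjamini-Hochberg adjustment over the 63169 unigenes tested. A unigene was called higher or lower at an adjusted p below 0.05. The 27913 unigenes left out held under 1% of the counts in any library. Fitted log2 fold changes use a prior count of 0.125. The SE given with them is approximate: the absolute log2 fold change divided by the square root of the F statistic. The p-values measure the spread between these samples and treat the 9 libraries as independent. If non-infected and infected samples came from the same fish, the fit leaves that pairing out. All control samples come from other fish than the infected ones, so infection and any difference in fish, tank or processing cannot be separated in comparisons with control skin.

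The test was tried on simulated counts drawn from the library sizes and unigene means of these data. With 200 of 63169 unigenes changed, 66% of those changed 32-fold and 28% of those changed 8-fold were recovered for infected against control skin, with 4 false calls among 51. For non-infected against control skin the shares were 62% and 32%, with 0 false calls among 48, and for infected against non-infected skin 58% and 28%, with 4 among 48. With 12000 changed, 4-fold changes were recovered in 48.9%, 51.1% and 50.3% of cases in the same order, and 2-fold changes in 9.00%, 10.9% and 9.30%. Small changes are therefore mostly missed at this number of samples.

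The design, the main test, the rule for naming unigenes and most alternatives were fixed before the data were examined. With no gene names, the rule names at most 2 unigenes that rose and 2 that fell per comparison, those with the smallest adjusted p, ties broken by the unadjusted p. The 33 gene lists fixed beforehand, for cytokines, complement, immune cells, keratins, mucus, muscle and other themes, one of them for ciliate transcripts, could not be matched to unigenes, and no list was tested. Alternatives that need names or species, and those meant for tables without counts, were not run. Alternatives covered scaling, the low-count filter, DESeq2 1.42.0 and limma-voom (limma 3.58.1), fits with only the groups compared, a replicate block, a fold change minimum and leaving out each library. Another 4 were chosen after seeing the data: the library totals behind the RPKM values, thinned counts, leaving out abundant unigenes, and removing a trend with length.

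Fold changes of infected and non-infected skin share the control libraries. For comparison, 20 sets of 9 unchanged libraries were simulated from the control means and the fitted spread of each unigene, with unigenes drawn independently. The controls could not be split into parts of 2 or more libraries each.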

Results

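Transcripts were counted in 9 libraries of orange-spotted grouper skin, 3 of them from control fish. Another 3 came from non-infected skin of fish infected locally with the ciliate *Cryptocaryon irritans*, and 3 from the infected skin of such fish. Control libraries held 36808364, 57525765 and 46620985 counts. Non-infected skin libraries held 49893832, 51689514 and 50482796 counts, and infected skin libraries 49999866, 48399389 and 51600333. Of 91082 unigenes, 63169 had enough counts to be tested, and these held between 99.5% and 99.8% of the counts of each library. The median length of a tested unigene was 1123 bases. The 50 most abundant unigenes of a library took 23.7% ± 3.13 (SD, n = 3) of its counts in control skin, 19.6% ± 1.11 (n = 3) in non-infected skin and 19.03% ± 1.46 (n = 3) in infected skin. The biological coefficient of variation over all tested unigenes was 53.1%. Unigenes are given by their identifiers in the deposited table, which does not pair them with gene names, species or genome positions. Fish and ciliate transcripts could therefore not be told apart, also among unigenes found mostly in infected skin.

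On average, libraries resembled those of their own group more than those of other groups. The mean Pearson correlation of log2 CPM across unigenes, which are not independent replicates, was 0.921 within control skin, 0.925 within non-infected skin and 0.903 within infected skin. It was 0.859 between control and non-infected skin, 0.868 between non-infected and infected skin and 0.764 between control and infected skin. Single pairs overlapped, since infected libraries 2 and 3 correlated at 0.888 and the closest pair of a non-infected and an infected library at 0.895. The first principal component held 47.2% of the variance and the second 13.3%. Scores on the first component were -222 ± 4.16 (SD, n = 3) in control skin, 9.87 ± 40.0 (n = 3) in non-infected skin and 212 ± 63.2 (n = 3) in infected skin. Non-infected skin scores ran from -33.2 to 45.8 and did not overlap those of either other group.

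**Figure D1:**
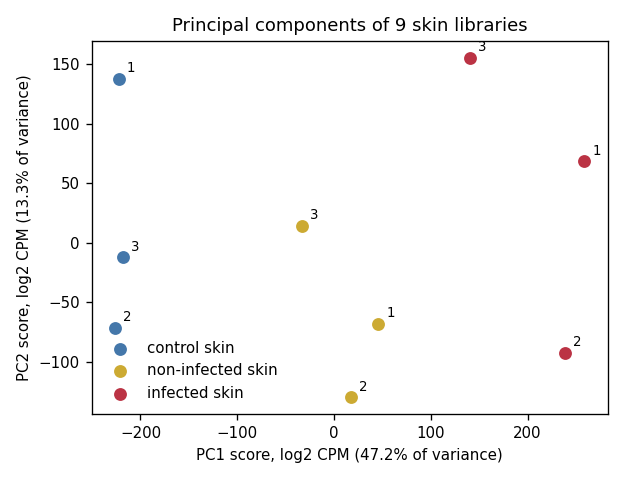
Scores of the 9 libraries on the first (x axis, 47.2% of variance) and second (y axis, 13.3%) principal component of log2 CPM, 1 point per library, coloured by group and numbered by replicate. Control libraries lie between -226 and -218 on the first component, non-infected skin between -33.2 and 45.8 and infected skin between 140 and 259.

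The first comparison asked which transcripts differ between the infected site and skin of control fish. Unigene seq000018809 (6435 bases) rose from 0.0740 ± 0.0439 CPM (SD, n = 3) in control skin to 514 ± 89.5 CPM (n = 3) in infected skin, a log2 fold change of 12.71 ± 0.68 (SE). Its control level rests on 10 counts in 3 libraries. Unigene seq000176731 (2706 bases) rose from 4.07 ± 0.267 CPM (n = 3) to 163 ± 32.3 CPM (n = 3), a log2 fold change of 5.32 ± 0.27 (SE). Unigene seq000040231 (483 bases) fell from 164 ± 5.48 CPM (n = 3) to 1.29 ± 0.216 CPM (n = 3), a log2 fold change of -6.98 ± 0.33 (SE). Unigene seq000008060 (2567 bases) fell from 38.8 ± 4.26 CPM (n = 3) to 2.09 ± 0.102 CPM (n = 3), a log2 fold change of -4.21 ± 0.22 (SE). The adjusted p of each of these 4 in edgeR's quasi-likelihood test was 0.000115, and the 3 libraries of each group lay apart from those of the other.

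Across all tested unigenes, 17818 (28.2%) differed between infected and control skin in edgeR's quasi-likelihood test. Of these, 8713 were higher in infected skin, with a median log2 fold change of 2.16, and 9105 were lower, with a median of -2.43. At least 4-fold differences were found for 4748 unigenes higher and 5680 lower, and at least 16-fold differences for 1471 higher and 1885 lower. Among the 12634 most abundant tested unigenes 3244 were higher and 2072 lower, and among the 12634 least abundant 957 were higher and 1281 lower. Unigenes higher in infected skin took 10.6% ± 0.894 (SD, n = 3) of the counts in control skin, 25.6% ± 2.98 (n = 3) in non-infected skin and 42.4% ± 1.69 (n = 3) in infected skin. Unigenes lower in infected skin took 33.3% ± 4.26, 15.3% ± 0.609 and 6.54% ± 0.558 in the same order (SD, n = 3 each). The infected and control shares were computed on the libraries that chose these unigenes and are not independent evidence. Without control library 3 the number of unigenes called fell to 11527, with 5432 higher. Without infected library 1 there were 6672 higher and 5632 lower. More unigenes were also higher than lower with DESeq2 size factors (9184 and 8692), with no low-count filter (9426 and 8786), and with 3 alternatives chosen after seeing the data: the totals behind the RPKM values (9130 and 8202), the length trend removed (9715 and 8320) and abundant unigenes left out (9128 and 8780). Which direction held more unigenes is therefore not settled. No gene names were paired with these unigenes, so no pathway or cell type was tested.

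**Figure D2:**
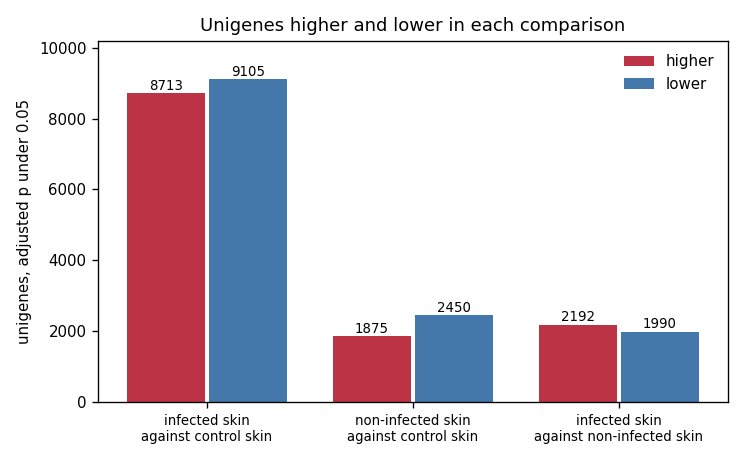
Number of unigenes (y axis, from 0) higher and lower at an adjusted p below 0.05 in each of the 3 comparisons (x axis), 1 bar per direction. Infected against control skin gave 8713 higher and 9105 lower, against 1875 and 2450 for non-infected against control skin and 2192 and 1990 for infected against non-infected skin.

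The second comparison asked which transcripts differ in skin away from the infected site, compared with control fish. Unigene seq000009901 (3443 bases) rose from 2.69 ± 0.0722 CPM (SD, n = 3) in control skin to 1543 ± 1033 CPM (n = 3) in non-infected skin, a log2 fold change of 9.16 ± 0.59 (SE), with an adjusted p of 0.000645 in edgeR's quasi-likelihood test. Without non-infected library 1, at 2727 CPM, the log2 fold change was 8.49. In infected skin the unigene reached 5776 ± 794 CPM (n = 3). Unigene seq000175100 (3638 bases) rose from 24.4 ± 4.49 CPM (n = 3) to 241 ± 12.7 CPM (n = 3), a log2 fold change of 3.31 ± 0.24 (SE) and an edgeR adjusted p of 0.000825. Unigene seq000040231 fell from 164 ± 5.48 CPM (n = 3) to 1.13 ± 0.379 CPM (n = 3), a log2 fold change of -7.17 ± 0.34 (SE) and an edgeR adjusted p of 0.000194. Unigene seq000035172 (503 bases) fell from 304 ± 112 CPM (n = 3) to 3.30 ± 0.723 CPM (n = 3), a log2 fold change of -6.52 ± 0.36 (SE) and an edgeR adjusted p of 0.000301. The last 2 were at 1.29 ± 0.216 and 3.97 ± 0.323 CPM (n = 3 each) in infected skin, and their difference between infected and non-infected skin did not pass the test (edgeR adjusted p of 0.724 and 0.623).

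In all, 4325 unigenes (6.85%) differed between non-infected and control skin, 1875 higher with a median log2 fold change of 2.06 and 2450 lower with a median of -2.62. Differences of at least 4-fold were found for 970 higher and 1644 lower. Unigenes higher in non-infected skin took 2.63% ± 0.158 (SD, n = 3) of the counts in control skin, 13.1% ± 2.48 (n = 3) in non-infected skin and 16.5% ± 0.749 (n = 3) in infected skin. Unigenes lower in non-infected skin took 14.5% ± 3.49, 2.86% ± 0.418 and 2.30% ± 0.128 in the same order (SD, n = 3 each). The share of called unigenes that were higher was 43.4% with TMM scaling, 57.2% with library size alone and 62.7% with the library totals behind the RPKM values, an alternative chosen after seeing the data, so the balance of directions moved with the scaling. It also turned without non-infected library 3 (56.2% higher), without infected library 1 (50.3%) and with no low-count filter (52.5%). Single libraries moved the number called: 1179 were higher without control library 1, and in all it was 2113 without control library 2, 1194 without control library 3, and 1029, 975 and 1760 without non-infected libraries 1, 2 and 3.

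Of the 4325 unigenes that differed between non-infected and control skin, 3559 (82.3%) also differed between infected and control skin in the same direction, 1530 higher and 2029 lower in both. Another 41 were called in opposite directions, a number that was 17, 10 and 6 without control libraries 1, 2 and 3, and 7, 8 and 12 without non-infected libraries 1, 2 and 3. Both comparisons use the same control libraries. Independent lists of these sizes would share 259 and 353. Simulated unchanged libraries gave a mean of 0.05 unigenes higher in both and 0 lower in both, but almost nothing is called where nothing changed, so these values do not measure the overlap that shared controls add. The correlation of the log2 fold changes across unigenes was 0.757, against 0.507 ± 0.00482 (SD over 20 draws) in simulated unchanged libraries. That SD comes from unigenes drawn independently, and between single libraries of the 2 skins, set against the mean of the controls, the correlation was 0.619 ± 0.0755 (SD over 9 pairs of libraries), for which the unchanged libraries gave 0.254. The covariance was 2.18, against 0.321 simulated, a difference of 1.86. The 3 control libraries could not be split into parts of 2 or more for these counts, so part of the overlap beyond independent lists may come from them. The number called in the same direction was 1844 without control library 2, 1043 without control library 3, and 915, 854 and 1542 without non-infected libraries 1, 2 and 3.

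**Figure D3:**
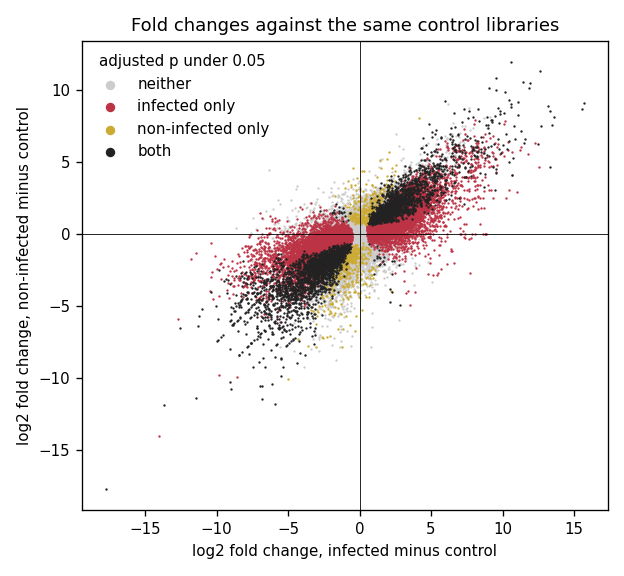
Log2 fold change against control skin of each tested unigene in infected skin (x axis) and non-infected skin (y axis), 1 point per unigene, coloured by the comparisons in which its adjusted p was below 0.05. The correlation across unigenes was 0.757, and 0.507 in simulated unchanged libraries that share controls.

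The third comparison set the infected site against non-infected skin of infected fish, and is also the test of whether the changes of the 2 skins from control differ. Unigene seq000176899 (11245 bases) was at 53.7 ± 7.05 CPM (SD, n = 3) in control skin, 12.4 ± 1.70 CPM (n = 3) in non-infected skin and 178 ± 10.6 CPM (n = 3) in infected skin. Its log2 difference between infected and non-infected skin was 3.84 ± 0.21 (SE), with an adjusted p of 0.000850 in edgeR's quasi-likelihood test. Unigene seq000017780 (1321 bases) rose from 0.826 ± 0.305 CPM (n = 3) in non-infected skin to 330 ± 160 CPM (n = 3) in infected skin, a log2 fold change of 8.63 ± 0.58 (SE) and an edgeR adjusted p of 0.00163. It had 4 counts in all in the control libraries. Unigene seq000001951 (3187 bases) fell from 4.18 ± 0.521 CPM (n = 3) to 0.126 ± 0.0503 CPM (n = 3), a log2 fold change of -5.03 ± 0.36 (SE) and an edgeR adjusted p of 0.00163. It was at 20.9 ± 4.99 CPM (n = 3) in control skin. Unigene seq000145475 (3763 bases) fell from 27.6 ± 2.90 CPM (n = 3) to 2.68 ± 0.622 CPM (n = 3), a log2 fold change of -3.36 ± 0.26 (SE) and an edgeR adjusted p of 0.00176, while control skin held 15.2 ± 2.59 CPM (n = 3).

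**Figure D4:**
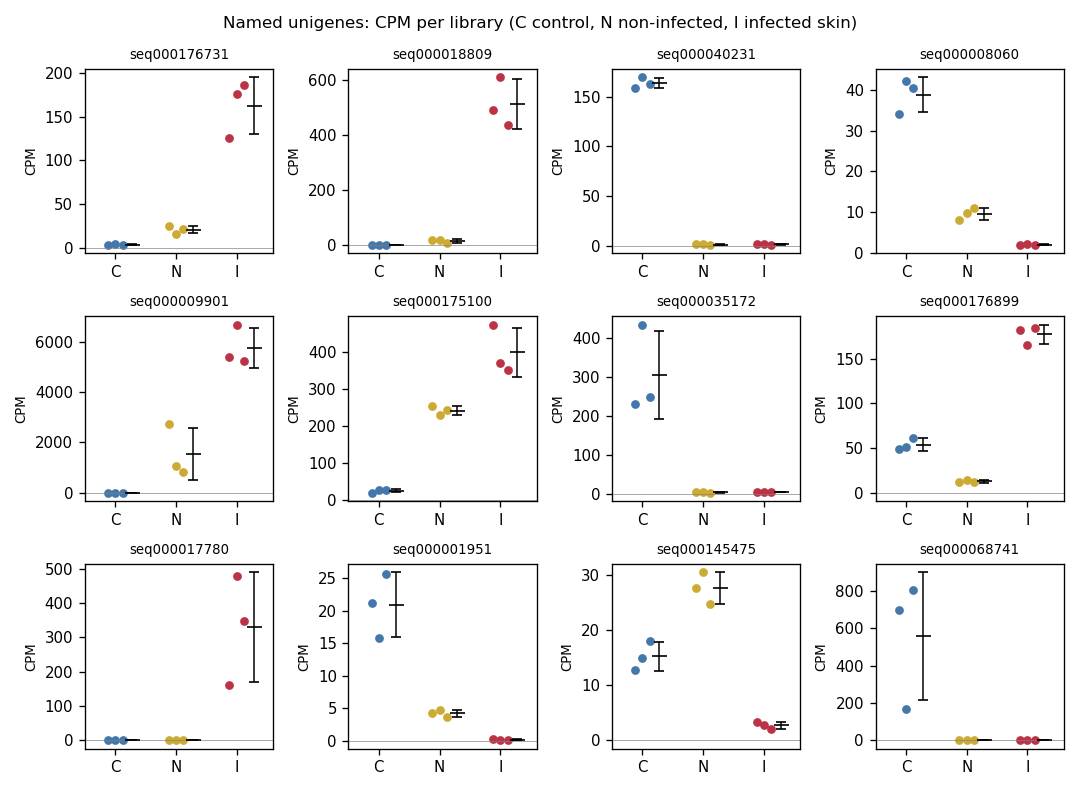
CPM (y axis, linear, a scale of its own per panel) of the 11 named unigenes and of seq000068741 in control (C), non-infected (N) and infected (I) skin, 1 point per library, with the mean and SD of each group as a dash and bar. Infected skin holds the highest mean for seq000009901 at 5776 CPM, and seq000068741 has 0 counts in the 6 libraries of infected fish.

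Between the 2 skins of infected fish, 4182 unigenes (6.62%) differed, 2192 higher in infected skin with a median log2 fold change of 2.02 and 1990 lower with a median of -2.09. At least 4-fold differences were found for 1107 higher and 1042 lower. Unigenes higher in infected than in non-infected skin took 4.57% ± 0.238 (SD, n = 3) of the counts in control skin, 6.09% ± 0.691 (n = 3) in non-infected skin and 19.7% ± 1.17 (n = 3) in infected skin. Unigenes lower in infected than in non-infected skin took 14.8% ± 2.63, 7.51% ± 0.688 and 1.83% ± 0.230 in the same order (SD, n = 3 each). As in the other comparisons, the shares of the groups compared come from the libraries that chose these unigenes. Infected skin differed from both other skins in the same direction for 3429 unigenes, 1814 higher and 1615 lower. Non-infected skin differed from both others for 341 unigenes, 160 higher and 181 lower. For 494 unigenes each step from control to non-infected to infected skin passed the test, 248 rising and 246 falling. Leaving out single libraries moved both numbers. The 341 became 224, 139 and 91 without control libraries 1, 2 and 3, 67, 62 and 83 without non-infected libraries 1, 2 and 3, and 178 without infected library 1. The 494 became 179 and 133 without control libraries 2 and 3, 90, 58 and 136 without non-infected libraries 1, 2 and 3, and 220 and 319 without infected libraries 1 and 2. DESeq2 gave 787 and 1187, and the replicate block 205 and 356. Of 14218 unigenes called in infected but not in non-infected skin against control, 2894 passed the direct test between the 2 skins, so for the others a difference between the skins was not shown. The share higher among those called was 52.4% with TMM scaling, 39.1% with library size alone and 38.9% with the totals behind the RPKM values. It was also 48.9%, 43.6% and 43.9% without non-infected libraries 1, 2 and 3, 45.4% without infected library 3 and 48.9% with no low-count filter. Without control library 2 there were 1255 lower, and without infected library 3 there were 1411 higher. The number called was 2330 without control library 3, 1435, 847 and 1181 without non-infected libraries 1, 2 and 3, and 1566 and 2612 without infected libraries 1 and 2. For infected skin against both others it was 2227 and 1814 without control libraries 2 and 3, 1274, 740 and 1036 without non-infected libraries 1, 2 and 3, and 1326 and 2192 without infected libraries 1 and 2.

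Unigene seq000068741 (10795 bases), chosen after its values were seen, had 26890, 8748 and 34055 counts in the control libraries and 0 in each of the 6 libraries of infected fish. Its control level was 557 ± 343 CPM (SD, n = 3), which is at least 57229-fold higher than the limit of 3 counts over those 6 libraries. The adjusted p in edgeR's quasi-likelihood test was 0.00122 for infected and 0.00465 for non-infected skin against control. Unigene seq000068741 is among those present only in control skin (see other observations). Fish of different stock could also give such unigenes, which cannot be told apart from infection here.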

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

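The tests of splits, of shared controls and of control fish kept apart were settled after the results were seen. What the test of mixed RNA should give was written before its value was computed. That test replaced an earlier one of mixing whose values in the same libraries had been seen, so it was not a blind prediction. The change from control differed between infected and non-infected skin, by the direct test between the 2 skins (edgeR, adjusted p below 0.05), in 8 of the 11 named unigenes. For seq000176899, seq000017780, seq000001951 and seq000145475 this was fixed beforehand, since they were named for their small adjusted p in that same test. The log2 difference, infected minus non-infected, was 2.93 for seq000176731, 5.19 for seq000018809, 1.90 for seq000009901, 3.84 for seq000176899 and 8.63 for seq000017780. It was -2.20 for seq000008060, -5.03 for seq000001951 and -3.36 for seq000145475.

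In 41 unigenes infected and non-infected skin moved in opposite directions from control, and each of them also passed the direct test between the 2 skins, which was all but fixed by choosing unigenes called in opposite directions. The number fell to 17, 10 and 6 without control libraries 1, 2 and 3 and to 7, 8 and 12 without non-infected libraries 1, 2 and 3, and was 23 with no low-count filter, 27 with the replicate block and 87 with DESeq2. In 22 of them infected skin was higher and non-infected skin lower than control, with median log2 fold changes of 1.52 and -1.86. In 19 infected skin was lower and non-infected skin higher, with medians of -1.40 and 1.499.

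The 3 comparisons gave 17818, 4325 and 4182 unigenes. Among the 10 splits of the 6 libraries of each comparison into 3 and 3, only the real one, 1 of 10, gave as many, and the highest of the others gave 0 with edgeR, the one tool run on the splits. At an unadjusted p below 0.05 the real splits gave 26192, 15413 and 15157 unigenes and the highest others 4754, 3160 and 4934. With 10 splits a share under 0.05 cannot be reached.

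On the control-to-infected axis, non-infected skin lay at 54.7% ± 9.27 (SD, n = 3) of the way, with different control libraries on the 2 sides. This argues against shared controls as the whole cause of a position between the other 2 skins. Non-infected skin also lay off that axis. Its distance from control skin was 63.7%, and from infected skin 55.8%, of the distance between control and infected skin. RNA of the infected site mixed into the non-infected samples would give 1 common share of the excess over control, yet across the 1530 unigenes higher in both the excess ratios of disjoint sets of libraries correlated at a mean of 0.527 (0.332 to 0.691 over 108 pairs of sets), against 0.00528 in draws with 1 share. That argues against such mixing as the whole cause, and a smaller part is not excluded. Control fish kept or processed apart cannot be told apart from infection: the changes from control to non-infected and from non-infected to infected skin had a mean cosine of 0.399 ± 0.193 (SD, n = 3), which is 2.06 SD above 0, and a limit of 2 SD written first was replaced by 3 SD once this was seen, since all controls are other fish. A response of skin away from the infected site may be part of the pattern and remains open.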

How the results depend on the processing

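The totals behind the RPKM values, thinning, leaving out abundant unigenes and removing a length trend were chosen after the data were seen. For the 11 named unigenes, 267 of 267 recomputed values kept their direction and side of the threshold. They were named for the smallest adjusted p in these same data, so this was all but fixed and does not measure how stable other calls are. DESeq2 called more: 9135 unigenes for non-infected and control skin, 8504 for the 2 skins of infected fish, 7016 changed alike from control in both skins and 6585 in infected skin against both others; the cause was not tested. For infected against control skin it called 25324. Leaving out 1 library gave 11527 to 18055 unigenes for infected and control skin, 975 to 4274 for non-infected and control skin, 847 to 4283 for the 2 skins of infected fish, 854 to 3403 changed alike and 740 to 3434 for infected skin against both others. Those fits have fewer samples. The first principal component held 62.1% of the variance with the 1000 most variable unigenes, and 45.7% to 51.5% without 1 library. With those 1000, infected library 3 scored 21.6, close to non-infected libraries 1 and 2 at 12.8 and 13.1. Infected libraries 1 and 2 scored 108 and 127. The correlation of fold changes was 0.769 to 0.792 without 1 control library. Unchanged libraries were simulated only with all 3 controls, so these values have no no-change value to be set against. Library size alone moved the median log2 fold change of all unigenes by 0.159 for non-infected against control skin and by -0.146 for infected against non-infected skin, and the totals behind the RPKM values by 0.221 and -0.157. Whether numbers pair the libraries is unsettled: deviations correlated above 0.1 in 4 of 9 same-numbered pairs, not in each, and own numbers correlated best in 9 of 18 combinations. Both counts include control libraries, which come from other fish. Between non-infected and infected skin the same-numbered pairs correlated at 0.0111, 0.448 and 0.228. Presence of unigenes went against the numbers for libraries 1 and 3, with 40 of 119 on own numbers and 117 on another matching (see other observations). Both matchings hold the 38 unigenes that joined 2 with 2. The replicate block uses the replicate numbers in all 3 groups, and no block by the presence matching was fitted. With the replicate block 16641, 2916 and 3028 unigenes were called in the 3 comparisons, and 3085 in the last with its 2 groups alone. Of the 2916, 1233 were higher in non-infected skin. Alternatives needing gene names, species or a table without counts were not run. Counts limit rare unigenes, of which 27913 were not tested.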

Other observations

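All tests here were chosen after the result was seen. Some unigenes were counted in 1 non-infected and 1 infected library and hardly in the other 4 libraries of infected fish. With at least 20 counts in both and at most 3 summed over the other 4, there were 119, of which 117 (98.3%) joined non-infected 1 with infected 3, 2 with 2, and 3 with 1. With at least 10 counts the number was 289 of 333 (86.8%), and the next best of the 6 possible matchings held 138. Unigenes missing from 1 library of each skin (at most 1 count summed) and at 20 or more counts in the other 4 numbered 80, all 80 on that matching. Between control and infected libraries the best matching held 17 of 34 and 60 of 119 unigenes present at 20 and 10 counts, close to the 16 and 54 of the next best. It held 17 of 26 and 52 of 73 unigenes missing, of which control 2 with infected 2 alone gave 11 and 38. Between control and non-infected libraries the best matchings held 19 of 43, 51 of 123, 8 of 20 and 25 of 55.

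Reads carried over between libraries add counts and remove none. The 80 joint absences still cannot decide against them, since a unigene of 2 libraries of 1 skin could be carried into their matched libraries. Carry-over therefore remains open. Depth differed little among the libraries of infected fish, from 48399389 to 51689514 counts, which argues against library depth. Thinning to the smallest library could therefore change little, and 99.0% at 20 counts and 91.5% at 10 counts stayed on the matching. A candidate explanation that remains open is that matched libraries come from the same fish or pool: over all tested unigenes the deviations from the group means of the matched pairs correlated at a mean of 0.192 (0.448 for 2 with 2, 0.145 for 3 with 1 and -0.0173 for 1 with 3), below the 0.229 of the matching by own number. The matching was used in no test between groups, so the edgeR tests took the libraries of infected fish as independent. Shared processing and an organism carried by single fish are untested.

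Other unigenes followed the fish groups. With at least 10 counts in each library of a group and at most 3 summed elsewhere, 87 were present only in control skin, 53 only in infected skin and 2 only in non-infected skin, against 12 for the highest of the 81 trios of mixed libraries. Unigenes missing from 1 group numbered 79 for control skin, 57 for infected skin and 1 for non-infected skin, against 39 for the highest mixed trio.

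For the unigenes present only in control skin, the highest mixed trio, 12, argues against differences between single libraries if all libraries are independent. If matched libraries share fish, a unigene of several control fish and an infected fish fills more than a trio, so the 12 cannot decide. Depth is argued against by the 89 found after thinning. For those missing from control skin, thinning to equal depth left 61, against 31 for the highest mixed trio. The 61 stayed above that trio but narrowly missed the margin set for this test, so depth is not settled. Differences between single libraries remain open, since before thinning a mixed trio lacked 39 against 79. Control and infected fish of different stock could also give the 87, and cannot be told apart from infection because all control libraries come from other fish.

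The deposited counts made up less of the library total behind the RPKM values in control skin, by -3.39 percentage points against the other 6 libraries (exact permutation test, two-sided p = 0.0119, the smallest that 84 splits can give). The test treats the libraries as independent. The labels do not say whether the infected and non-infected samples share fish, and if they do, this p is too small.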
